A study of Mus musculus with 12 samples.

How the data were processed

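Gene expression was measured by RNA sequencing in 12 libraries of mouse 4T1 cells in 4 groups of 3 libraries, named PBS, APAP, Oxa and OAP2 after their titles. The PBS libraries, whose treatment label reads DMSO, served as controls. Their values come from columns named CON with the numbers 1 to 3, read here as control and matched to the titles PBS by inference, as no other group lacks a drug. The labels describe an adherent wild-type cell line, while the series design text speaks of a cell-derived xenograft. Per the labels, RNA was extracted with Trizol, selected by poly(A), and sequenced in pairs from strand-marked (dUTP) libraries. The submitters' notes name cutadapt 1.9, HISAT2 2.2.1, StringTie 2.1.6, DESeq2 and edgeR without giving their roles. Doses, treatment times and the handling of reads that fit several genes are not given in the sources used here. The strand used for counting is not given either, so counts of overlapping or antisense genes, and of near-identical family members, are less certain than the rest.

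The deposited table holds, per the file headers, FPKM and a count for each gene and library. The deposited counts are estimated counts (expected_counts), whole numbers that the authors did not scale between libraries and that look like counts estimated by StringTie from transcript coverage after HISAT2 alignment. In 327 genes with a single transcript and FPKM above 20 in every library, the ratio of count to FPKM departed from a constant by a median of 0.00477%, and a count of 4 occurred 7655 times against 5992 times for 3 and 3357 times for 5. The deposited FPKM values (fpkm) were scaled by the authors to transcript length and to the mapped fragments of each library, and were used here for levels. The notes list genome build mm9, but of 29864 genes matched by identifier to GENCODE M21, 91.1% have the same chromosome, start and end as in GRCm38, so positions are given in GRCm38. The table lists 29937 genes, and 60 gene names are shared by more than 1 identifier.

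Genes with FPKM of at least 1 in at least 3 of the 12 libraries were tested, which left 12036 genes, the lowest with a mean count of 3.17. Counts were scaled by TMM and fitted in edgeR 4.0.16 (R 4.3.3) with 1 mean per group over all 12 libraries, by quasi-likelihood (glmQLFit, glmQLFTest), 2-sided. A gene was called at a Benjamini-Hochberg adjusted p below 0.05. The plan had named limma on log2(FPKM + 1) as the main test, with edgeR in its place if the file held raw counts. The file held whole-number counts, though estimated ones, so edgeR was taken as the main test and limma kept among the alternatives. The 5 comparisons were each treatment against PBS, OAP2 against Oxa and OAP2 against APAP. Standard errors (SE) of log2 fold changes were taken as the fold change divided by the square root of the F statistic, an approximation, and 95% intervals follow from them. Log2 CPM used a prior count of 2. The p-values measure only the spread between these libraries: nothing in the labels says whether replicates were separate cultures.

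Of 37 gene lists fixed before the data were examined, 25 cover pathways and 12 cell types. Lists with at least 5 tested genes (24) were tested with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01, adjusted over the lists of a comparison, and again with an estimated correlation and with fry. Members past the threshold were counted over all genes tested and adjusted over the list alone. Genes were named by a rule fixed beforehand: up to 12 largest rises and 12 largest falls among called genes whose 3 libraries of one group all lie above the 3 of the other, with a mean FPKM of at least 2 in the higher group. Predicted or unnamed genes and pseudogenes were left out. Where fewer than 10 genes passed, the 10 with the smallest p were taken, and from each list described up to 4 members with the largest test statistic, or 2 where none was called. Some genes that met the rule are not reported here.

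Depth ranged from 64071751 to 71500487 counts per library, and the common biological coefficient of variation was 18.1%. The fit was tested on simulated data with the fitted spread of each gene, the same in every group. For OAP2 against PBS it called 21 of 67 genes changed 1.5-fold, 52 of 67 changed 2-fold and 65 of 66 changed 4-fold, and 5 of 11836 unchanged genes. For APAP against PBS in the same simulated data set, the only one drawn, no gene had been changed and it called 0 of 12036. The simulated libraries varied independently, and none departed from its group as PBS 2 does, so these rates may not hold for the real comparisons. Agreement between treatment effects was set beside 20 simulations of unchanged groups that share the same controls. Replicate numbers did not pair the libraries: over 18 same-numbered pairs, the correlation of deviations from the group mean lay between -0.152 and 0.155.

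Alternatives set before the data were examined were other scalings, filters, pseudocounts and fold thresholds, array quality weights, a replicate block, a fit of only the 6 libraries compared, other list tests, and leaving out each library in turn. Added after seeing the data were DESeq2 1.42.0, removal of each library's trend with transcript length and GC, and leaving out PBS 2 and OAP2 3 together. The planned main test, limma on log2(FPKM + 1), became an alternative once the file was found to hold counts. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. All 12 libraries were used.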

Results

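Poly(A) RNA was sequenced from 12 libraries of 4T1 cells, a mouse mammary carcinoma line. Each of the groups PBS (controls), APAP, Oxa and OAP2 held 3 libraries. The total counts were 67653798, 69579384 and 65834234 for PBS 1 to 3, 64367096, 66223586 and 66781224 for APAP 1 to 3, 66237717, 64071751 and 66722910 for Oxa 1 to 3, and 70253687, 67741032 and 71500487 for OAP2 1 to 3. Levels are FPKM as mean ± SD (n = 3 libraries per group), changes are log2 fold changes ± SE, and adjusted p-values are from edgeR unless another tool is named. The series design sets OAP2 against the other treatments.

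The markers of epithelial cells were abundant in all 12 libraries, with a mean log2(FPKM + 1) between 5.73 and 6.23. Markers of red blood cells and of neutrophils stood at or below 0.09 in 11 libraries, but at 4.15 and 1.86 in PBS 2. In that control library, as members picked after their values were seen, the globin gene Hbb-bs reached FPKM 89.7 and the neutrophil gene S100a9 reached 35.5. The macrophage markers were highest in PBS 1, at 1.18 against 0.54 to 0.86 elsewhere. The fibroblast, endothelial, T and NK, B and plasma, dendritic, adipocyte, muscle and keratinocyte lists stayed at or below 0.82 in every library. In a principal component analysis of log2 CPM, the first component (26.8% of the variance) held the Oxa libraries between 23.61 and 33.84 and PBS 2 at 29.23. PBS 2 (-37.87) and OAP2 3 (-23.77) lay lowest on the second component (14.4%).

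**Figure D1:**
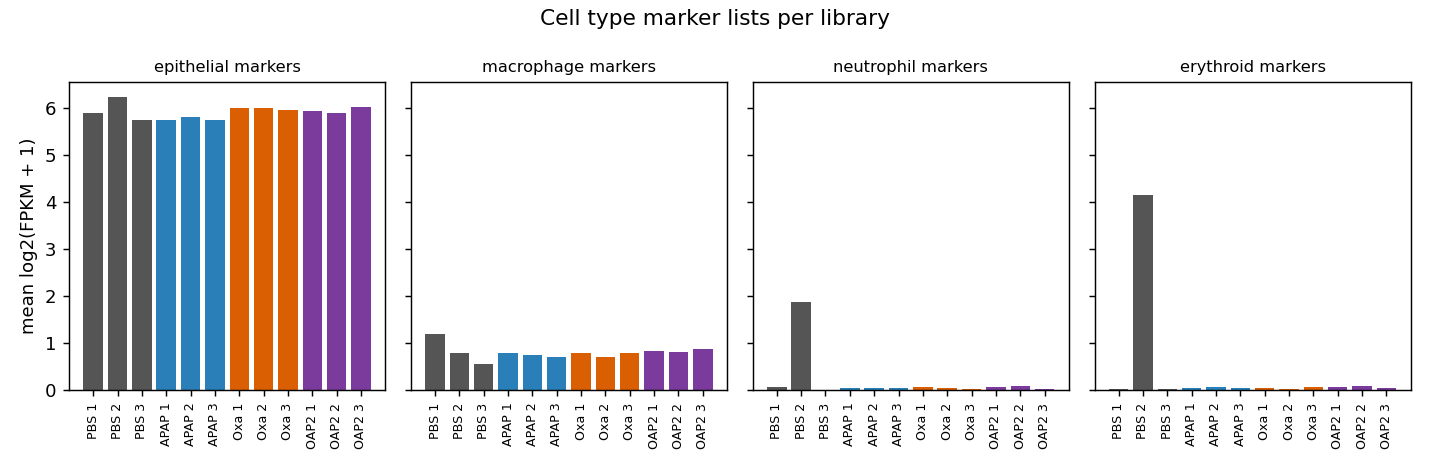
Mean log2(FPKM + 1) of 4 cell type marker lists in each of the 12 libraries, 1 bar per library. PBS 2 alone lies at 4.15 for erythroid and 1.86 for neutrophil markers, where the other 11 libraries are at or below 0.09.

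**Figure D2:**
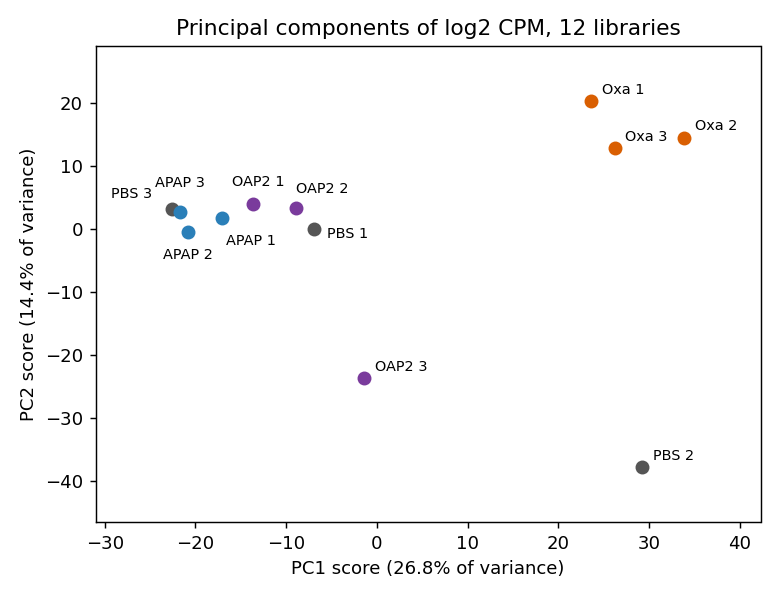
Scores of the 12 libraries on the first and second principal components of log2 CPM, coloured by group. The Oxa libraries lie between 23.61 and 33.84 on the first component, and PBS 2 lies at 29.23 and -37.87.

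OAP2 against PBS asks what OAP2 changed in these cells. Lcn2, a secreted lipocalin that binds iron-carrying siderophores (chromosome 2, 32384633 to 32387797), rose 6.88-fold from 2.52 ± 1.56 to 17.4 ± 6.02 (2.78 ± 0.43, adjusted p = 0.00310). Ephx1, the microsomal epoxide hydrolase, rose from 0.757 ± 0.286 to 3.68 ± 1.23 (2.28 ± 0.35, 0.00328), and the interferon-induced Isg15 from 6.48 ± 2.32 to 19.4 ± 2.21 (1.59 ± 0.25, adjusted p = 0.00366). In the other direction, Dsg3, a cadherin of desmosomes (chromosome 18, 20510274 to 20547459), fell from 12.6 ± 1.04 to 4.29 ± 0.155 (-1.55 ± 0.10, 1.17e-05). The kinase gene Plk2 fell from 66.8 ± 3.97 to 32.7 ± 0.991 (-1.02 ± 0.08, 6.49e-05), Serpinb2, a plasminogen activator inhibitor, from 15.0 ± 1.51 to 3.89 ± 1.5 (-1.93 ± 0.23, 0.000638), and Edn1, which encodes endothelin, from 9.91 ± 4.34 to 1.9 ± 0.41 (-2.36 ± 0.28, 0.000643).

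Of 12036 genes tested, OAP2 raised 258 and lowered 374, 632 in all, with 2499 at an unadjusted p below 0.05. The change was over 2-fold in 35 of the raised and 75 of the lowered genes. The other large rises were Zfp945 (1.49), the polycomb gene Cbx2 (1.44), the antiviral Rsad2 (1.40), Wfs1 of the endoplasmic reticulum (1.36), the small heat shock protein Cryab (1.34), Cd74, the invariant chain of MHC class II (1.33), Lrrc51 (1.24), Zfp566 (1.22) and Narf (1.22). The other large falls were the keratin Krt14 (-2.65), the neutrophil chemokines Cxcl1 (-2.61) and Cxcl5 (-2.57), the growth factor Ccn2 (-2.05), S100a7a (-1.97), the cathepsin Ctsw (-1.78), the matrix protein Thbs1 (-1.66), Rgs16 (-1.59) and the cyclooxygenase Ptgs2 (-1.57). By the naming rule, all 3 libraries of one group lay above all 3 of the other for each of these genes. Over all genes tested this held for 19.2%, where chance gives 10%. Without PBS 2 the falls were smaller, to -1.03 for Krt14, -1.24 for Cxcl1, -1.03 for Ccn2, -1.15 for Ctsw, -0.95 for Thbs1, -0.71 for Rgs16 and -0.65 for Ptgs2, all still called, and 1976 genes were called, with more rises (1055) than falls (921). Rises also outnumbered falls with array quality weights (1510 and 1326). Without OAP2 1, 252 genes were called, and without OAP2 2, 313. A fit of only the 6 libraries compared called 38 genes, 8 up and 30 down, and a fit with no filter on low values called 360. The calls of Cryab, Cd74, Lrrc51, Zfp566, Krt14, Cxcl1, Ccn2, Ctsw, Thbs1, Rgs16 and Ptgs2 each ended without OAP2 1, without OAP2 2 or without either in turn, with adjusted p up to 0.145.

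**Figure D3:**
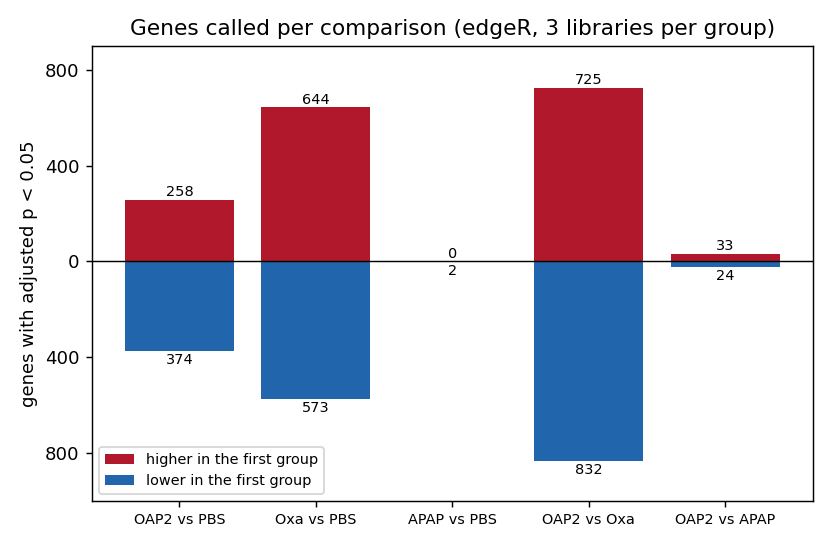
Genes called up and down in each of the 5 comparisons at an edgeR adjusted p below 0.05, of 12036 tested. OAP2 against PBS gave 258 up and 374 down, Oxa against PBS 644 and 573, and APAP against PBS 0 and 2.

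Genes of the type I interferon response were higher in OAP2. Of 14 tested, 4 rose, 0 fell and 10 did not pass (7 up and 0 down adjusted over the list alone): Isg15 (1.59), Rsad2 (1.40), the antiviral Oasl2 (1.11 ± 0.24, adjusted p = 0.0178, 0.0771 without OAP2 1) and the RNA sensor Ifih1 (0.91 ± 0.14, 0.00306). The list test gave an adjusted p of 1.13e-06 by camera, and an adjusted p of 0.0679 with an estimated correlation. Of 22 genes of the endoplasmic reticulum stress and amino acid response, 3 rose and 0 fell (4 and 0 adjusted over the list alone; camera adjusted p = 9.08e-05, adjusted p = 0.219 with an estimated correlation). These were the transcription factor Ddit3, from 32.3 ± 2.1 to 53.5 ± 2.71 (0.74 ± 0.09, 0.000654), the chaperone Hspa5, from 1188 ± 66.6 to 1980.2 ± 257 (0.75 ± 0.13, 0.00607), and the phosphatase subunit Ppp1r15a (0.52 ± 0.09, 0.00641).

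Further lists rose by camera. Of 22 NRF2 targets, Ephx1 and the ferritin light chain Ftl1 (0.57 ± 0.10, 0.00641) rose and 0 fell (3 and 0 adjusted over the list alone; camera adjusted p = 0.00214, adjusted p = 0.360 with an estimated correlation). Of 16 ferroptosis genes, Ftl1, the amino acid transporter subunit Slc3a2 (0.54 ± 0.11) and the biopterin enzyme Gch1 (0.74 ± 0.19) rose and Ptgs2 fell (7 and 2 adjusted over the list alone; 0.0206, adjusted p = 0.288 with an estimated correlation). Of 8 genes of platinum and copper transport and metallothioneins, Mt1 (0.40), Mt2 (0.76) and the efflux pump Abcc3 (1.21) rose and 0 fell (4 and 0 adjusted over the list alone; 0.0113, adjusted p = 0.142 with an estimated correlation). Of 18 autophagy and lysosome genes, the cargo receptor Sqstm1 (0.63 ± 0.09, 0.00245) and Map1lc3a (1.13 ± 0.25, 0.0212) rose and 0 fell (5 and 1 adjusted over the list alone; 0.0113, adjusted p = 0.133 with an estimated correlation). Of 20 hypoxia and glycolysis genes, Ndrg1 (0.56) rose and 0 fell (4 and 1 adjusted over the list alone; 0.0436, adjusted p = 0.408 with an estimated correlation). Without PBS 2 the transport list (0.0728), the autophagy list (0.0852) and the hypoxia list (0.0852) were no longer called, without PBS 3 the NRF2 (0.0798), ferroptosis (0.193) and hypoxia (0.274) lists, without OAP2 2 the hypoxia list (0.102), and without PBS 1 (0.0948) or OAP2 3 (0.0528) the ferroptosis list. The hypoxia list was also lost with limma on log2(FPKM + 0.1) (0.0646) and with the trend with transcript length and GC removed (0.0546). The calls of Gch1, Slc3a2, Mt1, Mt2, Abcc3, Map1lc3a and Ndrg1 ended without at least 1 library, with adjusted p up to 0.120.

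Inflammatory cytokines and NF-kB targets were lower in OAP2. Of 14 tested, 0 rose and 6 fell (1 and 7 adjusted over the list alone; camera adjusted p = 1.47e-05, adjusted p = 0.123 with an estimated correlation), among them Cxcl5, Cxcl1, the NF-kB inhibitor Tnfaip3 (-1.41 ± 0.18, 0.000956) and Csf3, the granulocyte growth factor (-0.86 ± 0.17, 0.0114). PBS 2, the library with the erythroid and neutrophil transcripts, held the highest level of Cxcl1 (FPKM 39.52 against 7.90 and 5.81 in PBS 1 and PBS 3). Of 9 immediate early genes, the phosphatase Dusp1 (-1.38 ± 0.21, 0.00292) and the transcription factors Klf6 (-0.76 ± 0.14) and Junb (-0.90 ± 0.22, -0.45 without PBS 2, 0.104 without OAP2 2) fell and 0 rose (0 and 5 adjusted over the list alone; 9.08e-05, adjusted p = 0.130 with an estimated correlation). Without PBS 2 this list was not called (0.0592). Of 8 arachidonic acid and prostaglandin genes, Ptgs2 and the phospholipase Pla2g4a (-0.64 ± 0.10, 0.00309) fell and 0 rose (0 and 4 adjusted over the list alone; 0.00125, adjusted p = 0.0679 with an estimated correlation). Of 10 mesenchymal transition and invasion genes, fibronectin Fn1 (-0.77 ± 0.13, 0.00607), from 336 ± 35.2 to 195 ± 36.9, and S100a4 (-1.44 ± 0.28, 0.0113) fell and 0 rose (0 and 4 adjusted over the list alone; 0.00214, adjusted p = 0.0679 with an estimated correlation). With PBS 2 and OAP2 3 both left out this list was not called (0.0880).

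**Figure D4:**
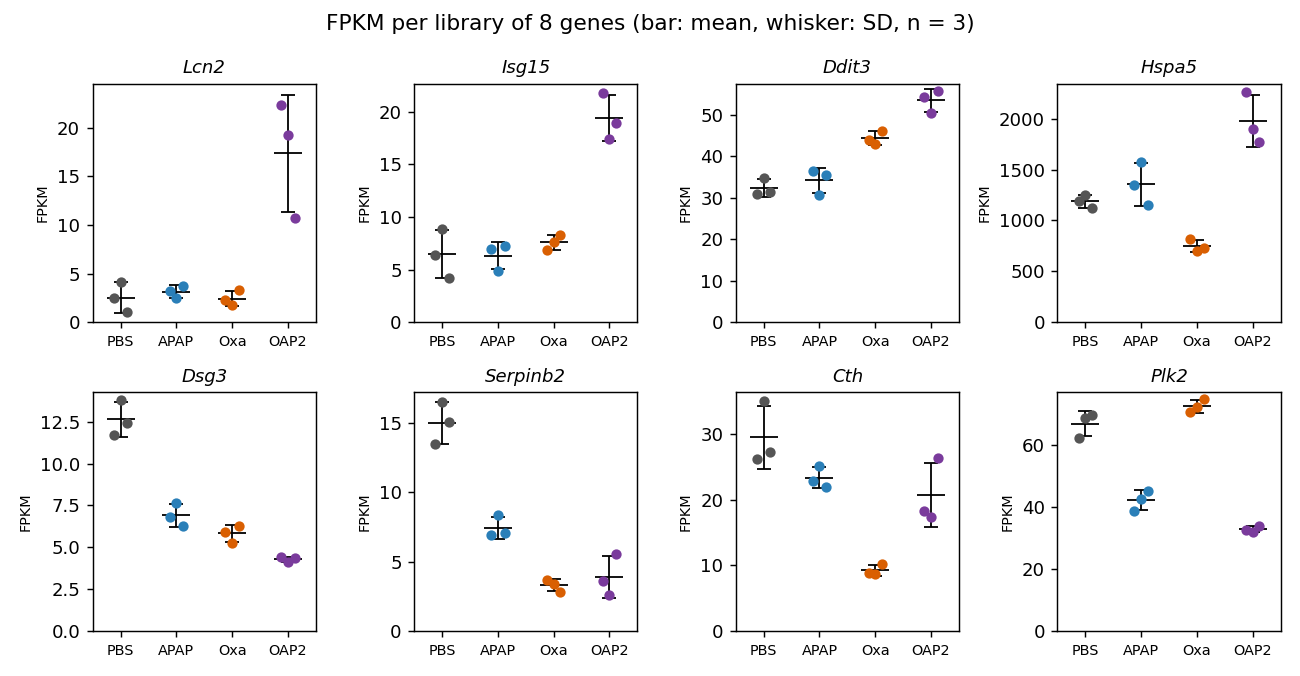
FPKM of 8 named genes in each library, with the group mean and SD (n = 3). Lcn2 and Isg15 are highest in OAP2 (means 17.4 and 19.4), Cth is lowest in Oxa (9.21), and Dsg3 falls from 12.6 in PBS to 6.90 in APAP, 5.82 in Oxa and 4.29 in OAP2.

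Oxa against PBS asks the same of Oxa. Cth, the enzyme that makes cysteine from cystathionine (chromosome 3, 157894248 to 157925077), fell from 29.5 ± 4.82 to 9.21 ± 0.809 (-1.67 ± 0.16, adjusted p = 0.000241). Serpinb2 fell from 15.0 ± 1.51 to 3.31 ± 0.443 (-2.16 ± 0.23, 0.000643), and the mitochondrial selenoprotein Selenoo from 3.34 ± 0.993 to 0.913 ± 0.112 (-1.85 ± 0.21, 0.000767). Cbx2 rose 3.08-fold, from 2.30 ± 0.467 to 7.06 ± 0.208 (1.62 ± 0.15, 0.000241). Tapbp, which loads peptides onto MHC class I (chromosome 17, 33915899 to 33926197), rose from 7.81 ± 3.17 to 22.5 ± 2.1 (1.53 ± 0.29, 0.00691), and the intermediate filament gene Vim rose 2.02-fold (1.02, 0.00302).

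Of 12036 genes, Oxa raised 644 and lowered 573, 1217 in all, with 3261 at an unadjusted p below 0.05. The change was over 2-fold in 70 of the raised and 86 of the lowered genes, and 30.3% of genes had groups that did not overlap, where chance gives 10%. The other large rises were the transglutaminase Tgm1 (1.76), the small nuclear RNA Rn7sk (1.62), CT010467 (1.45), Ctsw (1.45), Narf (1.41), the MYC network repressor Mnt (1.38), Nicn1 (1.36), the kinase Camkk1 (1.36), Pdcd4 (1.33), an inhibitor of translation, and Calcoco1 (1.31). The other large falls were the growth response factor Egr1 (-2.73), the carbonic anhydrase Car6 (-2.27), the ATP-gated channel P2rx3 (-1.85), the hexosamine enzyme Gnpnat1 (-1.65), Cox6a2 (-1.53), Serpinf1 (-1.46), the cytokine Tslp (-1.41), the antiproliferative gene Btg2 (-1.32) and Tmem171 (-1.31). Without PBS 2, Egr1 stood at -1.62 and Tslp at -0.75, both still called, and 3066 genes were called. Falls outnumbered rises without Oxa 1 (262 up and 274 down) and with the trend with transcript length and GC removed (758 and 850). Without Oxa 1, Oxa 2 or Oxa 3 the count was 536, 477 or 585, and without PBS 1 or PBS 3 it was 736 or 664. CT010467 dropped to 0.77 without Oxa 2 (0.190). The calls of Rn7sk, Ctsw, Camkk1, Cox6a2 and Tslp also ended without at least 1 library, with adjusted p up to 0.175.

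Of 32 cytosolic ribosomal protein genes, all had a negative value, 4 fell and 0 rose (0 up and 4 down adjusted over the list alone), with a median of -0.32. They were Rpl3, from 265 ± 27.8 to 159 ± 9.58 (-0.73, 0.00334), Rpl30 (-0.72), Rpl5 (-0.55, 0.0645 without Oxa 2) and Rps18 (-0.40, 0.119 without PBS 1). The camera adjusted p was 7.71e-07, and the adjusted p was 0.670 with an estimated correlation. Of 33 cell cycle and DNA replication genes, 6 rose and 0 fell (8 and 0 adjusted over the list alone; camera adjusted p = 0.00597, adjusted p = 0.670 with an estimated correlation), among them the kinetochore gene Cenpf (0.60), the mitotic kinesin Kif20a (0.45), the cyclin Ccne2 (0.56) and the checkpoint kinase Bub1 (0.32). Of 11 MHC class I presentation genes, Tapbp, the peptide transporter subunit Tap2 (1.13, 0.00863) and the immunoproteasome subunit Psmb8 (1.03, 0.0341) rose and 0 fell (4 and 1 adjusted over the list alone; 0.00597, adjusted p = 0.656 with an estimated correlation). The calls of Psmb8, Ccne2 and Bub1 ended without at least 1 library, with adjusted p up to 0.121.

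Of 9 immediate early genes, Egr1, Dusp1 (-1.14) and Klf6 (-0.52) fell and 0 rose (0 and 5 adjusted over the list alone; camera adjusted p = 0.00597, adjusted p = 0.656 with an estimated correlation). Of 17 cholesterol synthesis genes, Sqle (-0.50), Msmo1 (-0.62) and Lss (-0.66) fell and 0 rose (0 and 4 adjusted over the list alone; 0.0359, adjusted p = 0.670 with an estimated correlation). Pla2g4a (-0.39) was the 1 called member of the arachidonic acid list, of 8 tested (0 up and 2 down adjusted over the list alone; 0.0219, adjusted p = 0.453 with an estimated correlation). The mitochondrial mRNA mt-Nd2 (0.54) was the 1 called of 13 encoded in mitochondria (1 up and 0 down adjusted over the list alone; 0.0303, adjusted p = 0.755 with an estimated correlation). Without PBS 2, the library with the erythroid transcripts, none of these 4 lists was called, with adjusted p of 0.351, 0.768, 0.153 and 0.520, and the cholesterol list turned direction. The mitochondrial list was also lost without Oxa 1 (0.191) and after quantile normalization (0.729), and the cholesterol list without Oxa 3 (0.0950). With limma on log2(FPKM + 0.1) neither was called (0.0529 and 0.0678). Klf6 stood at -0.33 and Lss at -0.36 without PBS 2, and the calls of Klf6, Msmo1, Lss, Pla2g4a and mt-Nd2 ended without at least 1 Oxa library, with adjusted p up to 0.134.

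APAP against PBS gave 2 called genes, both lower in APAP. Dsg3 fell from 12.6 ± 1.04 to 6.90 ± 0.688 (-0.83 ± 0.10, 95% interval -1.05 to -0.62, adjusted p = 0.0163), and Plk2 fell from 66.8 ± 3.97 to 42.1 ± 3.19 (-0.62 ± 0.08, -0.80 to -0.45, 0.0210). All 3 APAP libraries lay below all 3 PBS libraries for both genes, which the naming rule also required. The next genes did not pass: Cavin2, a coat protein of caveolae (-1.09, 0.0564), the membrane protein Stom (-0.52), Cbx2 (0.93) and the plasminogen activator Plau (-1.04), each at 0.0628, and Tmem176a (-0.74), Cxcl5 (-2.09), Ankrd1 (-0.60) and Ifi203 (0.56), each at 0.157. An unadjusted p below 0.05 was reached by 1103 genes, DESeq2 called 97 and limma on log2(FPKM + 1) called 2. With no filter on low values, or with only the 6 libraries compared, 0 genes were called. Groups did not overlap for 16.2% of genes, where chance gives 10%. Without APAP 1 no gene was called (Dsg3 0.197, Plk2 0.301). Without APAP 3 neither Dsg3 nor Plk2 was called, the 1 gene called there being another, and the call of Plk2 also ended without APAP 2 and without PBS 3. Without PBS 2, Stom was called (-0.57, 0.0214) beside Dsg3 and Plk2.

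As sets, 8 lists were lower and 1 was higher in APAP by camera, though no member of them was called over all genes. All 14 inflammatory genes had negative values (0 up and 7 down adjusted over the list alone; camera adjusted p = 1.95e-08, adjusted p = 0.0531 with an estimated correlation), with Cxcl1 at -2.47 ± 0.57 and Cxcl5 at -2.09 ± 0.39. Cxcl1, looked up by library after its result had been seen, stood at FPKM 39.52 in PBS 2 and at 7.90 and 5.81 in PBS 1 and PBS 3, and without PBS 2 Cxcl1 was at -1.10 and Cxcl5 at -1.29. All 32 ribosomal protein genes had negative values, with a median of -0.17 (0 and 0 adjusted over the list alone; 7.17e-06, adjusted p = 0.644 with an estimated correlation). The mesenchymal list, with S100a4 at -1.13, had 0 up and 4 down adjusted over the list alone (0.000279, adjusted p = 0.0501 with an estimated correlation), and the arachidonic acid list, with Ptgs2 at -1.53 (-0.61 without PBS 2), had 0 and 2 (0.000621, adjusted p = 0.0501 with an estimated correlation). The nuclear oxidative phosphorylation list, 30 of 35 negative, was called at 0.000292 (adjusted p = 0.644 with an estimated correlation). The cholesterol list (0.00131), the immediate early list (0.00840) and the MHC class I list (0.0137) were lower, each with an adjusted p of 0.543 with an estimated correlation, and the mitochondrial mRNAs were higher (0.0236, adjusted p = 0.770 with an estimated correlation). Without PBS 2 the cholesterol (0.726), immediate early (0.465), MHC class I (0.107) and mitochondrial (0.977) lists were not called, the endoplasmic reticulum stress (0.000104), heat shock (0.0176) and ribosome biogenesis (0.0195) lists were called higher, and neither without APAP 3 (0.0835) nor after quantile normalization (0.848) was the mitochondrial list called. Without PBS 3 the epithelial (0.00923), NRF2 (0.0181), xenobiotic (0.0362) and cell cycle (0.0423) lists were called lower as well, making 13 lists called, and the ribosome biogenesis list was also called after quantile normalization (0.0292).

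OAP2 against Oxa compares these treatments directly. Lcn2 was 17.4 ± 6.02 in OAP2 and 2.42 ± 0.796 in Oxa (2.85 ± 0.43, adjusted p = 0.00129). Hspa5 was 1980.2 ± 257 in OAP2 and 748 ± 59.6 in Oxa, a 2.66-fold difference (1.41 ± 0.13, 0.000109), and it rose in OAP2 (0.75) and fell in Oxa (-0.66) against PBS. Plk2 was lower in OAP2 at 32.7 ± 0.991 against 72.4 ± 2.09 (-1.14 ± 0.08, 3.77e-05), as was Cavin2 at 1.24 ± 0.135 against 5.00 ± 0.915 (-2.00 ± 0.17, 6.98e-05). Edn1 was 1.9 ± 0.41 in OAP2 and 8.45 ± 0.34 in Oxa (-2.14 ± 0.28, 0.000582), and Ctsw 0.903 ± 0.204 and 8.56 ± 1.20 (-3.23 ± 0.38, 0.000325).

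Of 12036 genes, 725 were higher and 832 lower in OAP2 than in Oxa, 1557 in all, with 3346 at an unadjusted p below 0.05. The difference was over 2-fold in 117 and 107 of them, and 36.4% of genes had groups that did not overlap, where chance gives 10%. Also higher in OAP2 were Sh2d6 (4.84, FPKM 0.07 in Oxa and 2.04 in OAP2), Car6 (3.12), Rsad2 (2.42), the progestin and adipoQ receptor Paqr3 (2.17), Egr1 (2.04), Fam171b (2.01), the chemokine Ccl5 (1.89), Mir1668 (1.85), the desmosomal Cdsn (1.80), Gnpnat1 (1.78) and Hhipl1 (1.73). Also lower were Tgm1 (-2.31), the matrix protein Ltbp2 (-2.25), Cxcl5 (-2.15), Krt14 (-2.11), Podnl1 (-2.09), the anchoring collagen Col7a1 (-2.08), Ccn2 (-1.96), the mitochondrial tRNA gene mt-Ti (-1.94) and Il18rap (-1.88). Without Oxa 1, Oxa 2, Oxa 3 or OAP2 1 the count was 776, 688, 891 or 875. More genes were higher than lower in OAP2 without Oxa 1 (440 and 336), Oxa 2 (380 and 308), Oxa 3 (463 and 428) or OAP2 3 (804 and 697), and the numbers were 970 and 969 with the trend with transcript length and GC removed. The calls of Egr1, Mir1668, Krt14, mt-Ti and Il18rap ended without at least 1 library, with adjusted p up to 0.171.

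Interferon response genes were higher in OAP2 than in Oxa. Of 14 tested, 8 were higher and 2 lower (8 and 2 adjusted over the list alone; camera adjusted p = 5.87e-05, adjusted p = 0.184 with an estimated correlation), with Rsad2 (2.42), Oasl1 (1.65), Oasl2 (1.42) and Ifih1 (1.13) at the top. Of 22 genes of the endoplasmic reticulum stress list, Hspa5, Ppp1r15a (0.63), the asparagine synthetase Asns (0.55) and Xbp1 (0.39) were higher and 0 lower (5 and 0 adjusted over the list alone; 0.000947, adjusted p = 0.428 with an estimated correlation). Of 32 ribosomal protein genes, 31 had positive values with a median of 0.25, and Rpl3 (0.59) alone was called (1 and 0 adjusted over the list alone; 0.000947, adjusted p = 0.717 with an estimated correlation). Of 22 NRF2 targets, 5 were higher and 0 lower (7 and 0 adjusted over the list alone; 0.0450, adjusted p = 0.659 with an estimated correlation), among them the quinone reductase Nqo1 (1.48), Srxn1 (0.49) and the cystine transporter Slc7a11 (0.86). Of 16 ferroptosis genes, Slc3a2 (0.76), Gch1 (1.25), Slc7a11 and Fth1 (0.40) were higher and 0 lower (6 and 1 adjusted over the list alone; 0.0475, adjusted p = 0.428 with an estimated correlation). Of 8 xenobiotic metabolism genes, Nqo1 and Gstp1 (0.43) were higher and 0 lower (3 and 0 adjusted over the list alone; 0.0382, adjusted p = 0.428 with an estimated correlation). Without OAP2 3 the ribosomal (0.745), NRF2 (0.130), ferroptosis (0.113) and xenobiotic (0.108) lists were not called. The NRF2 list was also lost without Oxa 1 (0.0716) or Oxa 2 (0.0514), the ferroptosis list without Oxa 1 (0.0933), Oxa 2 (0.0514) or Oxa 3 (0.0566), and the xenobiotic list without Oxa 2 (0.0699). The NRF2 and ferroptosis lists were not called after quantile normalization (0.0886 and 0.170), with limma on log2(FPKM + 0.1) (0.0762 and 0.0918) or with the trend with transcript length and GC removed (0.0512 each), nor was the xenobiotic list with that trend removed (0.0604). The calls of Xbp1, Slc7a11, Fth1 and Gstp1 ended without at least 1 library, with adjusted p up to 0.0987.

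Cell cycle genes were lower in OAP2 than in Oxa: of 33 tested, 0 were higher and 9 lower (0 and 12 adjusted over the list alone; camera adjusted p = 0.00435, adjusted p = 0.659 with an estimated correlation), among them the transcription factor E2f1 (-0.66), the replication licensing gene Cdc6 (-0.95), Kif20a (-0.44) and Ccne2 (-0.57, 0.0524 without Oxa 3). Of 10 mesenchymal genes, Vim (-0.95), S100a4 (-1.65), Mmp9 (-1.61) and Zeb2 (-0.36) were lower and 0 higher (0 and 5 adjusted over the list alone; 0.000947, adjusted p = 0.0964 with an estimated correlation). Of 14 inflammatory genes, Ccl5 was higher, and Cxcl5, Cxcl3 (-1.70) and Tnfaip3 (-0.70) were lower (1 and 5 adjusted over the list alone; 0.0147, adjusted p = 0.428 with an estimated correlation, and 0.159 by camera without OAP2 3). The calls of Mmp9, Zeb2 and Tnfaip3 ended without at least 1 library, with adjusted p up to 0.153.

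OAP2 against APAP gave 57 called genes, 33 higher and 24 lower in OAP2. Lcn2 was 17.4 ± 6.02 in OAP2 and 3.13 ± 0.667 in APAP (2.45 ± 0.42, adjusted p = 0.0283), Isg15 19.4 ± 2.21 and 6.32 ± 1.31 (1.59 ± 0.25, 0.0247), and the protease inhibitor Slpi 57.4 ± 3.01 and 25.2 ± 1.36 (1.16 ± 0.16, 0.0147). Sox9, a transcription factor (chromosome 11, 112782224 to 112787760), was 8.94 ± 0.519 in OAP2 and 17.1 ± 1.76 in APAP (-0.97 ± 0.11, 0.00723), and Dsg3 was lower again (-0.72, 0.0147). Also higher were Ephx1 (2.01), Caml (1.09), Tmem176a (0.89), Trafd1 (0.86), the secreted chaperone Clu (0.82), Tmx4 (0.80), Rabac1 (0.74), Hacd2 (0.71) and the tetraspanin Cd82 (0.66), and also lower were Dusp1 (-1.25), Syne3 (-1.04), Spsb1 (-0.85), Dusp8 (-0.79), Csrnp1 (-0.79), Ccbe1 (-0.76), B4galt2 (-0.75), Sf3a3 (-0.65), Fosl2 (-0.64) and Col8a1 (-0.59). An unadjusted p below 0.05 was reached by 1835 genes, DESeq2 called 506, and groups did not overlap for 25.7% of genes, where chance gives 10%. With no filter on low values 4 genes were called, 0 higher and 4 lower, and with a replicate block 30, of which 20 were higher and 10 lower. With only the 6 libraries compared the count was 286. Plk2 (-0.39, 95% interval -0.57 to -0.21, 0.0616) and Hspa5 (0.52, 0.24 to 0.79, 0.0940) did not pass. No gene was called without APAP 2, where Sox9 had 0.0620. The counts were 2 and 5 without APAP 1 and APAP 3, and 3, 1 and 125 without OAP2 1, OAP2 2 and OAP2 3. Lower genes outnumbered higher ones in each of these except without OAP2 3, and each of the 27 named genes called here lost its call without at least 1 library, with adjusted p up to 0.257.

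By camera, 11 lists were higher and 1 lower in OAP2 than in APAP. All 14 interferon genes had positive values, with 1 called over all genes and 9 up and 0 down adjusted over the list alone (camera adjusted p = 2.40e-10, adjusted p = 0.0591 with an estimated correlation). The endoplasmic reticulum stress list had 1 called, Ddit3 (0.62), and 7 up and 0 down adjusted over the list alone (3.68e-07, adjusted p = 0.124 with an estimated correlation). All 22 NRF2 targets had positive values, with Ephx1 called and 4 up and 0 down adjusted over the list alone (1.79e-06, adjusted p = 0.161 with an estimated correlation). The MHC class I list had 1 called, its light chain B2m (0.65, 0.0252), and 5 up and 0 down adjusted over the list alone (1.25e-05, adjusted p = 0.124 with an estimated correlation). The ferroptosis (0.000585), autophagy (0.000661), epithelial (0.0108) and transport (0.0335) lists had 0 members called over all genes and 4, 4, 4 and 3 up and 0 down adjusted over the list alone, with adjusted p of 0.124, 0.0985, 0.295 and 0.217 with an estimated correlation. The xenobiotic list had Ephx1 called and 2 up adjusted over the list alone (0.00474, adjusted p = 0.124 with an estimated correlation), and the immediate early list had Dusp1 called and 3 down (0.0189, adjusted p = 0.341 with an estimated correlation). The oxidative phosphorylation (0.0108) and ribosomal protein (0.0476) lists, with adjusted p of 0.737 and 0.801 with an estimated correlation and 0 members called either way, turned direction without OAP2 3 (0.814 and 0.0204) and were not called without APAP 1 (0.147 and 0.401) or with the trend with transcript length and GC removed (0.205 and 0.472). The ribosomal list was also lost after quantile normalization (0.528) and with limma on log2(FPKM + 0.1) (0.0823). With PBS 2 and OAP2 3 both left out, the immediate early (0.102) and xenobiotic (0.0811) lists were not called. The epithelial list was not called without OAP2 3 (0.0588) or after quantile normalization (0.0893), and the transport list without OAP2 1 (0.153), OAP2 2 (0.0783), APAP 1 (0.0884) or APAP 3 (0.0781), after quantile normalization (0.0688), with limma on log2(FPKM + 0.1) (0.0823) or with the trend removed (0.0672).

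The treatment effects against PBS were compared across the 12036 genes, which are not independent replicates, and which share the same 3 controls in each pair. OAP2 and Oxa raised 75 genes in common, among them Cbx2 and Narf, and lowered 95, among them Serpinb2. Independent calls would give 13.8 and 17.8, a reference that leaves out the shared controls. In 20 simulations of unchanged groups with shared controls, a mean of 1.65 genes was called in both, a reference that leaves out the effects. Neither is the number expected by chance here, so part of the shared calls may come from the shared control libraries. The correlation of their effects was 0.360 (Spearman 0.367), against a mean of 0.648 in the simulations, and the covariance was 0.0606 against 0.0517. For OAP2 and APAP the correlation was 0.637 (Spearman 0.478) against 0.655, the covariance was 0.0877 against 0.0522, and Dsg3 and Plk2 were lowered by both. For Oxa and APAP the correlation was 0.191 (Spearman 0.132) against 0.647, and the covariance was 0.0268 against 0.0511. No split of 3 controls leaves 2 for each effect and none was run, so part of the covariances above the simulated value, those of OAP2 with Oxa and with APAP, may still come from the shared libraries.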

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

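The tests on fibroblast and endothelial genes and on the median epithelial gene were chosen after the results had been seen.

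Red blood cell and neutrophil markers, in genes too low elsewhere to be tested, reached a mean log2(FPKM + 1) of 4.15 and 1.86 in PBS 2, above the other 11 libraries, which lay at or below 0.09. Of 15 further blood and bone marrow genes chosen before their values were seen, 6 (40.0%) stood out in PBS 2, short of the majority set beforehand for RNA of blood or marrow cells and above the 10% set against it, so that source cannot be told apart from others, the share lying between the bounds. Of 11 further intestinal genes, 8 (72.7%) stood out, at FPKM of at most 0.74 (Zg16), so RNA of intestine or of a tissue that shares these transcripts is a candidate source. The lowest of the 8 lay near the floor, with Cdx1 and Phgr1 at 0.1, Fcgbp at 0.11 and Fabp2 at 0.13. Of 16 fibroblast and endothelial genes, 4 (25.0%) stood out (Col1a2, Col3a1, Dcn and Lum), all 4 from the fibroblast list and none from the endothelial list, so host stroma stays open as a source. Beyond these sources of RNA no biological explanation was tested, since no group in the design holds this library alone.

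Tumour cell genes also differed in PBS 2: 590 genes lay over 2-fold below and 309 over 2-fold above the mean of PBS 1 and PBS 3, and, as examples picked after their values were seen, Il1a (FPKM 178.41 against 18.90 and 9.32) and Hspa8 (371.9 against 85.39 and 67.05) were among the higher ones in FPKM. The median epithelial marker was 0.40 log2 units higher in PBS 2 than in the other controls. That argues against dilution of the tumour cells by RNA of non-epithelial cells as the whole cause of the lower genes. An epithelial source such as intestine could carry these markers itself, so the test cannot decide on dilution by it. A trend with transcript length or GC is argued against as the whole cause as well: with each library's trend removed, 83.1% of the lower and 92.6% of the higher genes stayed over 2-fold apart. A different state of the cells in this library, or a different history of the culture or sample, stays open and was not tested.

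In the comparison of OAP2 with Oxa, the ribosomal protein list was higher and the mesenchymal list lower in OAP2. The departures of OAP2 2 and OAP2 3 from the mean of the other OAP2 libraries went with transcript length in opposite directions (Spearman 0.414 and -0.342 across genes). Departures within a group balance each other, so the opposite signs are partly built in. With each library's trend removed, camera gave both lists an adjusted p of 0.00113 (0.000947 before), and their medians went from 0.25 to 0.21 and from -0.40 to -0.42, which argues against the trend as the whole cause. With an estimated correlation neither list was called (0.717 and 0.0964). The ribosomal list was not called without OAP2 3 either (0.745), and was then lower in OAP2 than in PBS (1.30e-08, 0.174 with all libraries), whereas the mesenchymal list was called without each library in turn. A treatment difference stays open for both, as does any other property of OAP2 3 for the ribosomal list.

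OAP2 and Oxa moved 24 genes in opposite directions against PBS, 13 of them up in OAP2 and 11 up in Oxa. Each was also called in the direct comparison. That comparison is the difference between the effects against PBS, so with opposite signs its call adds no separate support. Independent calls would give 12.3 and 20, and the simulations of unchanged groups with shared controls gave a mean of 0. The first of these values leaves out the shared controls and the second the effects, so neither is the number expected by chance here. Among the 24 were Ctsw (-1.78 in OAP2, 1.45 in Oxa), Rsad2 (1.40, -1.02), Paqr3 (0.98, -1.18), Ltbp2 (-1.26, 0.99), the lymphatic growth factor Vegfc (-0.88, 0.61), Slpi (0.83, -0.54), Hspa5 (0.75, -0.66), the oxidoreductase Ero1l (0.60, -0.55) and the adhesion molecule Vcam1 (-0.51, 0.41). Of the 24, 2 (Hspa5 and Ero1l) stayed called in opposite directions without each library in turn, while the others, Ctsw and Rsad2 included, lost a call without at least 1 library, and 5 were kept without PBS 1 and 5 without Oxa 2.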

How the results depend on the processing

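Results with DESeq2, the length and GC trend removed, and PBS 2 and OAP2 3 left out together were chosen after the data had been seen. The main test first planned was limma on log2(FPKM + 1). The cause of the changes listed here was not tested unless the setting itself changes which genes or libraries are tested. In the order OAP2, Oxa and APAP against PBS, OAP2 against Oxa and OAP2 against APAP, the counts of 632, 1217, 2, 1557 and 57 genes became 360, 701, 0, 1026 and 4 with no filter on low values, 2836, 4394, 105, 3474 and 1567 with array quality weights, 110, 156, 0, 224 and 9 with a log2 fold change of at least 1, and 2838, 4258, 72, 3426 and 1438 with PBS 2 and OAP2 3 left out. Of the genes called with all libraries, 617, 1213, 2, 1540 and 57 were also called with those libraries left out. DESeq2 gave 1267, 2020 and 97 against PBS and 506 for OAP2 against APAP, the OAP2 against Oxa count staying within 1.5-fold. With only the 6 libraries compared the counts were 38, 523 and 0 against PBS and 286 for OAP2 against APAP. Removing the length and GC trend gave 1003 for OAP2 and 7 for APAP against PBS and 108 for OAP2 against APAP. A replicate block, though the numbers did not pair the libraries, gave 30 for OAP2 against APAP. Leaving out each library in turn gave 252 (without OAP2 1) to 1976 (without PBS 2), 477 (Oxa 2) to 3066 (PBS 2), 0 (APAP 1) to 3 (PBS 1, PBS 2 or PBS 3), 688 (Oxa 2) to 1501 (OAP2 3) and 0 (APAP 2) to 125 (OAP2 3). The counts stayed within 1.5-fold under both other scalings, both pseudocounts and a mean FPKM of at least 5. The share of called genes that rose went from 40.8% to 48.4% with DESeq2 and 53.1% with those libraries left out for OAP2 against PBS, and from 57.9% to 71.9% with limma on log2(FPKM + 1) for OAP2 against APAP. With an estimated correlation 0 lists were called in any comparison, and fry called 1 for Oxa and 2 for APAP against PBS and 7 for OAP2 against APAP. The correlation of effects went, for OAP2 and Oxa, from 0.360 to 0.394 with quantile normalization, 0.405 with a mean FPKM of at least 5 and 0.442 with PBS 2 and OAP2 3 left out. For OAP2 and APAP it went from 0.637 to 0.585 with quantile normalization and 0.754 with a mean FPKM of at least 5, and for Oxa and APAP from 0.191 to 0.333 with a mean FPKM of at least 5 and 0.325 with those libraries left out. Among named genes and lists called before or after a change of setting, the direction turned only with PBS 2 or OAP2 3 left out. With both left out, Hspa8 in APAP against PBS went from -0.64 to 0.56, and list tests turned for endoplasmic reticulum stress (adjusted p = 0.0144 in Oxa, 6.76e-05 in APAP), cholesterol synthesis in Oxa (0.768), heat shock in APAP (0.0402), and oxidative phosphorylation (0.854) and ribosomal proteins (0.0419) in OAP2 against APAP. Without PBS 2 alone the endoplasmic reticulum stress list turned at 0.0111 in Oxa (range over left-out libraries 0.0111 to 0.945) and 0.000104 in APAP (0.000104 to 0.827), cholesterol synthesis at 0.768 (0.000871 to 0.768) and heat shock at 0.0176 (0.0176 to 0.797). Without OAP2 3 alone oxidative phosphorylation turned at 0.814 (1.41e-06 to 0.814) and ribosomal proteins at 0.0204 (3.16e-07 to 0.401). With PBS 2 and OAP2 3 both left out, further lists that lost their call were autophagy (0.128), immediate early (0.113), mesenchymal (0.0880) and hypoxia (0.0525) in OAP2, immediate early (0.342), arachidonic acid (0.0981) and mitochondrial (0.466) in Oxa, and cholesterol (0.738), immediate early (0.539), MHC class I (0.147) and mitochondrial (0.950) in APAP, each against PBS. In OAP2 against Oxa they were ribosomal proteins (0.701), ferroptosis (0.249), NRF2 (0.186) and xenobiotic metabolism (0.186), and in OAP2 against APAP immediate early (0.102), epithelial (0.0811) and xenobiotic metabolism (0.0811). Calls gained with PBS 2 and OAP2 3 both left out were, against PBS, ribosomal proteins (3.05e-06) and MHC class I (0.000507) in OAP2, DNA repair (0.0144) in Oxa and ribosome biogenesis (0.0142) in APAP. They were also transport (0.00226) and oxidative phosphorylation (0.0303) in OAP2 against Oxa, and ribosome biogenesis (0.00130) in OAP2 against APAP. Further calls gained without OAP2 3 were, for OAP2 against PBS, MHC class I (0.00264), oxidative phosphorylation (0.00830), ribosome biogenesis (0.0166) and mitochondrial mRNAs (0.0292), and for OAP2 against Oxa transport (0.0166) and oxidative phosphorylation (0.0201). Without OAP2 1 mitochondrial mRNAs were called against Oxa (0.000546) and APAP (0.000590), and DNA repair against Oxa (0.0355). For OAP2 against PBS cholesterol synthesis was called without PBS 1 (0.0243) or PBS 3 (0.00618), and ribosome biogenesis without PBS 3 (0.0124). For Oxa against PBS, ribosome biogenesis (0.00710) and inflammatory genes (0.0321) were called without PBS 3, DNA repair without Oxa 2 (0.0351), and hypoxia genes without PBS 1 (0.0103) or Oxa 2 (0.0195) or after quantile normalization (0.00559). Ribosome biogenesis in OAP2 against APAP was called without OAP2 3 (0.00132), APAP 2 (0.0400) or APAP 3 (0.0322) and after quantile normalization (0.00205). Of the named genes called, 29 of 60, 34 of 76, 0 of 2, 45 of 83 and 0 of 27 were called without each library in turn. In the simulation of OAP2 against PBS, 2-fold changes were called in 77.6% and 1.5-fold changes in 31.3% of genes, so smaller changes were not reliably detectable there. The simulation gave every group the same spread and held no departing library, so these shares may differ in the real comparisons.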

Other observations

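The values of Lyz2 and Hspa8 in single libraries were picked after they had been seen, while the tests were set beforehand. Several lists did not pass as sets although single members were called. Of 18 p53 target genes, Plk2 alone was called for OAP2 against PBS (list adjusted p = 0.889; median 0.06 and mean -0.02), and in Oxa the cyclin-dependent kinase inhibitor Cdkn1a fell by 0.74 and Btg2 by 1.32 (list adjusted p = 0.940), Cdkn1a losing its call without Oxa 2 (0.0966). Of 30 genes of DNA crosslink and excision repair, 5 rose in Oxa and 1 fell (6 and 2 adjusted over the list alone; list adjusted p = 0.0585, and 0.0111 without PBS 2). The crosslink repair gene Fancd2 rose by 0.57, while the excision nuclease subunit Ercc1 fell by 0.62 (0.00930). Ercc1 was higher in OAP2 than in Oxa (0.71, 0.00314), and Fancd2 (-0.68), Fancg (-1.07) and Fanci (-0.87) were lower. The call of Fancd2 in Oxa against PBS ended without Oxa 3 (0.0797).

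The immune checkpoint genes had too few members expressed for a list test. Cd47, which restrains phagocytosis, rose in OAP2 from 16 ± 1.12 to 25.0 ± 1.96 FPKM (0.66 ± 0.10, adjusted p = 0.00266). Tigit was 86.9 ± 8.35 in PBS and 51.5 ± 16.9 in OAP2 (-0.74, 0.0287, and 0.118 without OAP2 2). Among epithelial markers, Krt19 (0.64) and Epcam (0.54) rose and Krt14 fell in OAP2 (list 0.247), Krt19 and Epcam losing their calls without OAP2 1 (0.0664 and 0.0639). In apoptosis genes the survival factor Mcl1 fell in Oxa (-0.41, 0.00691) and Bcl2l1 in OAP2 (-0.63, 0.0212, and 0.0962 without OAP2 1), with list tests at 0.505 and 0.542. No member of the heat shock list was called for OAP2 or Oxa against PBS (list 0.715 and 0.505), though without PBS 2 the list was called higher in both (0.0242 and 0.0354). In OAP2 the list's median was -0.05 and its mean 0.08, and Hspa8 ranged from 67.05 to 371.9 FPKM among the PBS libraries.

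Lyz2, a lysozyme gene of macrophages, varied among the controls, with FPKM 31.01 in PBS 1, 6.23 in PBS 2 and 0 in PBS 3, and lay between 4.65 and 9.27 in the 9 treated libraries.

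Splits of the 6 libraries of each comparison into 3 and 3 number 10, the real one counting as 1, which is too few for a share under 0.05. Each of the other splits mixes libraries of both groups, so a treatment difference adds to the spread within its groups. Low counts in them are therefore largely built in and give no measure of chance. The real and the highest other count of genes were 632 and 19 for OAP2 against PBS, 1217 and 2 for Oxa against PBS, 2 and 1 for APAP against PBS, 1557 and 0 for OAP2 against Oxa, and 57 and 1 for OAP2 against APAP.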
